A study of Homo sapiens with 4 samples.

How the data were processed

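Total RNA was taken from MDA-MB-231 cells infected with shRNA lentivirus and, per the labels, selected with puromycin for 5 days from 4 days after infection. Per the labels' protocols, RNA was treated with DNase, ribosomal RNA was removed and stranded total RNA libraries were made. Per the submitters' processing notes, reads were aligned with BWA to hg19. The version of BWA, the read counter, its use of strand, the annotation release, any filter and the scaling are not given in the sources used here. The 2 deposited tables each hold 1 knockdown and its own scrambled control, as log2 values per RefSeq transcript that the authors computed, over the same 27710 rows. Columns were given to samples by the titles in the labels, and each knockdown's control by its source name. 0 columns were left unused.

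The antilog of every deposited value was a whole number of reads, or a whole multiple of 1 factor per library, for 100% of values within 0.1 reads. The factor was 1.06 for control 1, 1.25 for the PRMT5 shRNA library and 1 for the others, which brings the column totals of each table close together. Tables were thus scaled separately. Every row has at least 100 reads in 1 or both libraries of the PRMT5 table, whereas the row maximum in the WDR77 table goes down to 24, so genes seen mainly in the WDR77 set could be missing from both. No row lies on the mitochondrial chromosome.

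From these values, rows on alternate or unplaced contigs (302) and repeated rows (9) were left out, and antilogs were summed per symbol to 14285 genes, 13406 of them with a coding transcript. Reads shared by isoforms count in each row. Within a pair the log2 ratio is on the authors' scale with no pseudocount, since no value was 0. Between tables, values are CPM of each library's gene total. A gene was counted if its mean over the libraries compared was at least 1 CPM and 20 reads. The design had assigned that floor to counts and genes above the median level to other units; the count floor was used because whole reads were recovered, and the other is among the alternatives. Genes at least 2-fold higher or lower were counted, and no p-value was computed for 1 library against 1. The counting SE of a gene uses its transcript row with the most reads, and intervals of the targeted genes are exact binomial (Clopper-Pearson) at 95%. Both cover counting error only, and PCR copies are not independent molecules.

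The pairs were compared by Pearson and Spearman correlation across genes and by the overlap of the 2-fold lists against that of independent lists. Each of 30 gene lists was fixed before the data were examined. A list's median was placed among 10000 random lists of the same size matched on deciles of level, as a description of these libraries. A percentile says nothing about how another culture would vary. A test across libraries used limma 3.58.1 in R 4.3.3, with a mean-dependent prior (trend), on log2 CPM of 13745 genes. It compared either shRNA with control with the control set as a term, and each shRNA with both controls in 3 groups, each with 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. Nothing in the labels says that the controls came from separate cultures, so these p-values measure only the spread between these libraries. That spread is mostly pooled over genes of like level. The prior had 24.8 degrees of freedom in the either-shRNA fit and was infinite in the 3-group fit. A gene's own spread thus counts little in the former and not at all in the latter. In the 3-group fit the lone knockdown library is assumed to vary like the controls. Where a count at an unadjusted p below 0.05 is given, it is a smaller share of the 13745 genes than 0.05. In the fits that gave these counts the distance between the sets enters the error, so unchanged genes need not give a share of 0.05. Such a count is thus no sign of a response and no sign that a response is absent.

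Named genes follow a rule fixed before the data were examined. It takes PRMT5 and WDR77, the 10 highest and 10 lowest coding genes per knockdown, the 10 highest and 10 lowest in both, the 5 most apart in each direction, and up to 4 members per list with the largest mean ratio. Any other gene is marked as chosen after its values were seen.

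On data simulated from the real means with 100 genes changed 2-fold and 100 changed 4-fold, those changed 4-fold reached the 2-fold rule in 100% of cases and those changed 2-fold in 56% (WDR77 pair) and 54% (PRMT5 pair), with 0 unchanged genes of 13745. A gene changed exactly 2-fold lies on the cutoff, so the shares of 56% and 54% follow from the rule and are no recovery rate. The limma test of either shRNA recovered 100% of genes changed 2-fold and 4-fold, with 5 unchanged genes called. The simulated change was the same in both knockdowns, whose disagreement is the error of that test. The real ratios correlated at only 0.199 across genes, so that recovery does not carry over to genes where the knockdowns differ. The tests against both controls recovered 0%. Poisson simulation of unchanged libraries gave 0 genes past 2-fold in any of 20 draws.

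Alternatives covered the floor, scaling by median of ratios, a 3-fold rule, the other set's control or the mean of both controls, the row with the most reads in place of the sum, and leaving out libraries. The fits with 1 library left out had no control-set term. The alternative pseudocount was not run because log values took none. Lowess trends (span 0.3) on transcript length and GC content were also taken off. GC content came from GENCODE v29 transcripts matched by RefSeq identifier, for 97.0% of genes in the WDR77 pair, and no coordinates were taken from that annotation, whose build differs from hg19. Coordinates are those of the tables, as 1-based positions on hg19. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.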

Results

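RNA was measured in MDA-MB-231, an established triple-negative breast cancer cell line, after lentiviral delivery of short hairpin RNAs (shRNAs) against WDR77 or PRMT5. PRMT5 is the main enzyme that places symmetric dimethyl marks on arginine, on histones and on splicing proteins such as the Sm proteins, and WDR77 (also called MEP50) is the WD-repeat partner that binds PRMT5 and its substrates. The series holds 4 total RNA libraries depleted of ribosomal RNA: 1 with WDR77 shRNA, 1 with PRMT5 shRNA, and 2 with a scrambled shRNA, of which control 1 belongs to the WDR77 knockdown and control 2 to the PRMT5 knockdown. Each knockdown therefore has 1 library and no replicate, so a difference from its own control carries no p-value and is described by size, as at least 2-fold. Reads summed over the transcript rows came to 118777035 in control 1, 125598674 in the WDR77 shRNA library, 174707352 in control 2 and 139672737 in the PRMT5 shRNA library, with reads shared by isoforms counted in each. At these depths the median counting error (SE) of a gene's log2 ratio was 0.05 in the WDR77 pair and 0.04 in the PRMT5 pair. That error covers counting only and says nothing about variation between cultures.

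The targeted genes were measured first, in every library. PRMT5 (chromosome 14, 23389733 to 23398661, minus strand, hg19) has a pair of RefSeq transcripts in the tables, NM_001039619 and NM_006109. In the PRMT5 shRNA library they stood at 11.6% (95% exact interval 11 to 12.4) and 11.2% (10.5 to 11.8) of their own control, and summed over both the log2 ratio was -3.13. In the WDR77 shRNA library PRMT5 RNA was at 85.0% (82.1 to 88.0) and 85.3% (82.4 to 88.3) of its control. WDR77 (NM_024102, chromosome 1, 111982512 to 111991830, minus strand) was at 18.6% (17.2 to 20) of its control in the WDR77 shRNA library, a log2 ratio of -2.43. In the PRMT5 shRNA library WDR77 RNA was also lower, at 42.4% (40.5 to 44.4) of control, a log2 ratio of -1.24. Each library thus carried less of the RNA its label names. Against the other set's scrambled control, the log2 ratio was -2.72 for PRMT5 in its own knockdown and -2.69 for WDR77 in its own.

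**Figure D1:**
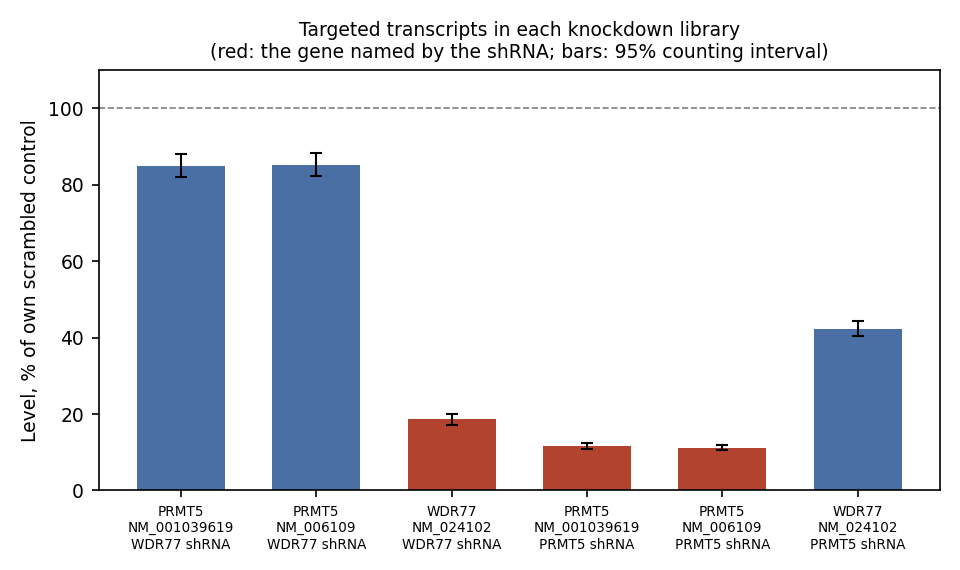
Level of each targeted transcript (y axis, % of the library's own scrambled control, starting at 0) by transcript and knockdown library (x axis), 1 library per bar; red bars are the gene the shRNA names, blue bars the partner gene, and error bars are exact 95% counting intervals. PRMT5 transcripts stand at 11.2% and 11.6% in the PRMT5 shRNA library and WDR77 at 18.6% in the WDR77 shRNA library, while WDR77 is at 42.4% in the PRMT5 shRNA library.

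The first comparison asked what the loss of either partner had in common, taking the knockdowns as a pair of cases of 1 complex, each against its own control. Genes that rose include the cytokine genes CXCL8, CSF2 and IL6, and genes that fell include GINS4, MCM4 and POLA1, which act in DNA replication. S100P, a calcium-binding protein often expressed in carcinomas, rose 10.0-fold on average, with log2 ratios of 3.42 after WDR77 shRNA and 3.22 after PRMT5 shRNA. Its level was low, at 0.34 CPM in control 1 and 0.26 in control 2, against 3.63 after WDR77 shRNA and 2.45 after PRMT5 shRNA. The neutrophil chemokine gene CXCL8 rose with log2 ratios of 1.79 and 2.22, CSF2, which encodes GM-CSF, with 1.88 and 2.04, and IL6 with 1.33 and 1.95. NR1D1, a repressor in the circadian clock, had 2.21 and 1.76, and PER1, another clock gene, 1.44 and 1.64. Among the genes that fell, GINS4 of the replicative helicase had -1.24 and -1.53, MCM4 -0.79 and -1.85, the polymerase alpha subunit gene POLA1 -0.78 and -1.64, and CCNE2, a G1/S cyclin, -0.86 and -1.46 (WDR77 and PRMT5 shRNA, in that order). Control 1 over control 2 was -3.57 for IL6, -2.08 for CSF2, -3.49 for PER1 and -2.09 for NR1D1, against 0.35 for S100P and 0.09 for CXCL8. With control 2 in place of control 1 the direction after WDR77 shRNA turned for IL6 (-2.23), CSF2 (-0.20) and PER1 (-2.04). It was kept for S100P (3.78), CXCL8 (1.89), GINS4 (-1.33), MCM4 (-1.06) and POLA1 (-1.13), and kept at a smaller size for NR1D1 (0.12) and CCNE2 (-0.21).

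In limma's moderated test on log2 CPM, with the control set as a term, 51 of 13745 genes passed a Benjamini-Hochberg adjusted p of 0.05, 36 higher and 15 lower, with adjusted p from 0.000251 to 0.0447. Adjusted p was 0.00025 for S100P and for CXCL8, 0.000966 for CSF2, 0.00114 for NR1D1, 0.00383 for IL6, 0.0385 for PER1, 0.00979 for GINS4, 0.0129 for MCM4, 0.0387 for POLA1 and 0.0447 for CCNE2. All 51 went the same way in both libraries and 33 were at least 2-fold in each. The 15 lower include the targeted genes, WDR77 (-2.43 and -1.24, adjusted p 0.00142) and PRMT5 (-0.23 and -3.13, adjusted p 0.0387). The test itself favours a shared direction, since disagreement between the knockdowns is its error. Besides those above, the rule named GDF15 (1.43 and 4.68, adjusted p 0.00142), NNMT (1.18 and 3.08, adjusted p 0.00126), DDIT4 (1.25 and 2.06, adjusted p 0.00128), TRIM29 (2.14 and 1.60, adjusted p 0.00230), JUNB (1.58 and 1.5, adjusted p 0.00847) and CXCL2 (1.96 and 1.66, adjusted p 0.00847) among those that rose. SDC1, encoding syndecan-1 (-0.97 and -2.0, adjusted p 0.00588), the replication-linked gene FAM111B (-1.11 and -1.62, adjusted p 0.00612), FZD3 (-1.32 and -1.30, adjusted p 0.0378), SLAIN1 (-1.38 and -1.26, adjusted p 0.0183) and C14orf37 (-1.57 and -1.85, adjusted p 0.0378) fell. Of the 51, 28 were named by the fixed rule. EGR1 (2.13 and 1.77, adjusted p 0.00676) and DUSP1 (1.28 and 2.04, adjusted p 0.00256), immediate-early genes, and the chemokine gene CXCL1 (1.80 and 1.18, adjusted p 0.0296) are named after their values were seen. With the other set's control their ratios after WDR77 shRNA turned to -2.98, -0.28 and -2.07. With that control CXCL2 (-0.011) and FAM111B (0.027) turned too, and TRIM29 (0.018), JUNB (0.55), FZD3 (-0.07) and SLAIN1 (-0.91) were smaller. The fit has 1 residual degree of freedom and an error pooled mostly over genes (24.8 prior degrees of freedom). It tests the mean of the knockdowns, so a gene can pass on 1 library, as ASNS did with log2 ratios of 0.11 and 3.64. With median-of-ratios scaling only CSF2, CXCL8, NR1D1 and S100P passed. With no term for the control set 0 genes passed in limma, with 21 at an unadjusted p below 0.05. The fits with 1 library left out also had no such term and left a lone library in a group. They are not the same test on fewer libraries, so how the 51 calls depend on any 1 library was not tested.

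**Figure D2:**
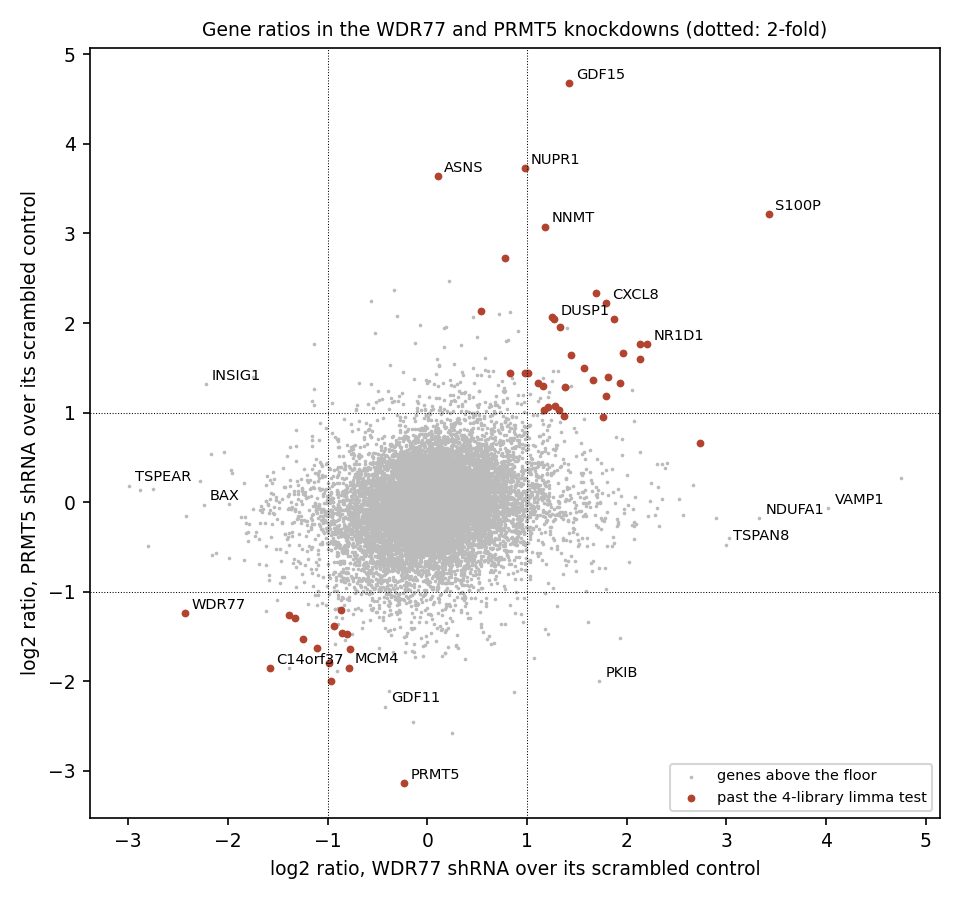
Gene ratios in both knockdowns: log2 ratio of WDR77 shRNA over its scrambled control (x axis) against log2 ratio of PRMT5 shRNA over its own (y axis), 1 point per gene above the floor; red points are the 51 genes past the 4-library limma test and dotted lines mark 2-fold. The called genes lie mostly in the upper right, with S100P at 3.42 and 3.22, and GDF15 and ASNS lie high on the PRMT5 axis at 4.68 and 3.64.

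Gene lists fixed beforehand cover the same groups with more members. They are not separate evidence for IL6, MCM4, POLA1 and CCNE2, which were named above through their rank in these lists. For NF-kB cytokines and targets, the median log2 ratio over 22 members was 1.02 after WDR77 shRNA and 0.72 after PRMT5 shRNA, and both lay at percentile 100 of 10000 random lists matched on level, as a description of these libraries. In that list 11 and 7 members were at least 2-fold higher, and 1 and 0 at least 2-fold lower, the 1 being IL11 (-2.04 and 0.56), named after its values were seen. IL1A also went opposite ways (-0.33 and 2.37). In limma's test of either shRNA, 5 of 24 members rose over all genes tested, and 15 rose and 1 fell when adjusted over the list alone. The list also differed between the controls, with a median of -1.58 for control 1 over control 2, and against the other set's control the WDR77 median was -1.26. E2F and replication genes had medians of -0.40 and -0.61 over 38 members, both at percentile 0, with 37 and 35 members below their control. Of these genes 3 fell over all genes tested (CCNE2, MCM4 and POLA1) and 18 fell when adjusted over the list alone. G2/M and mitosis genes had medians of -0.54 and -0.25 over 36 members (percentiles 0 and 0.02), where CENPE had -1.32 and -0.72, and KIF20A -0.84 and -1.14. None of that list passed over all genes tested, and 4 fell when adjusted over the list alone. Its median for control 1 over control 2 was 0.67, and with the other set's control the WDR77 median turned to 0.11 and CENPE to 0.51. Homologous recombination and Fanconi repair genes had medians of -0.29 and -0.32 over 30 members, each at percentile 0.02, with FANCD2 at -0.86 and -0.87 and BRIP1 at -0.87 and -0.78. With the other set's control these were -0.33 for FANCD2 and 0.66 for BRIP1 after WDR77 shRNA. Here 0 passed over all genes tested and 6 fell when adjusted over the list alone.

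Across the 13196 genes above the floor in both pairs, the knockdown ratios correlated weakly, with a Pearson r of 0.199 and a Spearman rho of 0.2 across genes, which are not independent replicates. The sign was the same for 56.2% of genes. At the 2-fold rule 38 genes were higher in both, where independent lists of those sizes would share 7.89, and 16 were lower in both, where they would share 6.5. Within deciles of level the corresponding expectations were 8.72 and 7.68. The pairs share no library. With the mean of both controls as a common reference the r became -0.408, and with the other set's control -0.807.

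Against its own control, the PRMT5 shRNA library had 220 genes at least 2-fold higher and 300 at least 2-fold lower among 13561 above the floor. Of the 10 highest, ASNS, CHAC1 and TRIB3 belong to the fixed ATF4 and unfolded protein response list. GDF15, a stress-induced cytokine of the TGF-beta family (chromosome 19, 18496968 to 18499986), was 25.7-fold higher, at log2 4.68 ± 0.12 (counting SE). NUPR1, a stress-induced chromatin protein, was at 3.73 ± 0.13, ASNS, asparagine synthetase (chromosome 7, 97481429 to 97501854), at 3.64 ± 0.03, and CHAC1, which degrades glutathione, at 3.0 ± 0.13. TRIB3, a pseudokinase induced by ATF4, was at 2.25 ± 0.04. S100P (3.22 ± 0.23), NNMT, nicotinamide N-methyltransferase (3.08 ± 0.06), the lactate carrier gene SLC16A1 (2.72 ± 0.15), IL1A (2.37 ± 0.05) and CXCL8 (2.22 ± 0.03) completed the 10 highest.

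The lowest after PRMT5 itself was CYB561A3 (-2.58 ± 0.05), followed by MID1, a microtubule-associated ubiquitin ligase (-2.45 ± 0.05). GDF11 (-2.28 ± 0.09), GPR39 (-2.12 ± 0.13), MAGED1 (-2.11 ± 0.04), SDC1 (-2.0 ± 0.03), PKIB, an inhibitor of protein kinase A (-2.0 ± 0.18), NEURL1B (-1.88 ± 0.10) and C14orf37 (-1.85 ± 0.14) followed. Between the scrambled controls, control 1 over control 2, several of these genes also differed by more than 2-fold, with log2 2.34 for NNMT, -2.27 for GDF11 and -1.73 for CYB561A3, whereas GDF15, ASNS and TRIB3 stood at -0.07, 0.22 and 0.10. With control 1 in place of control 2 the ratio was 0.73 for NNMT, -0.016 for GDF11, -0.85 for CYB561A3 and 1.65 for SLC16A1.

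The ATF4 and unfolded protein response list had a median of 0.95 after PRMT5 shRNA, at percentile 100, with 14 of 29 members at least 2-fold higher and 0 at least 2-fold lower. Among them were ATF3 (2.07), DDIT4 (2.06), PPP1R15A (1.40) and ASNS (3.64). In limma's test of either shRNA 2 of 30 members rose, DDIT4 and ASNS, and 15 rose when adjusted over the list alone. After WDR77 shRNA the list median was 0.25 (percentile 98.8), and 0.19 (percentile 96.9), inside the central 95%, with length and GC trends taken off. Interferon-stimulated genes had a median of -0.55 over 36 members (percentile 0), with 7 at least 2-fold lower and 1 at least 2-fold higher, and a median of -0.18 after WDR77 shRNA (percentile 0.71), where 3 were at least 2-fold higher and 0 at least 2-fold lower. Those 3, named after their values were seen, were OAS1 (1.66), IFI6 (1.03) and IFI27 (1.02). The WDR77 median of the list turned to 0.62 with the other set's control, and was -0.11 (percentile 3.66) with length and GC trends taken off. In limma's test of either shRNA 0 of 37 passed and 1 fell, IFIT1, when adjusted over the list alone. Among them OASL was at -1.66, IFI44 at -1.47, IFIT1 at -1.34 and OAS2 at -1.2. Apoptosis regulators had a median of 0.28 over 24 members (percentile 99.9), where BBC3, which encodes PUMA, was at 1.81. After WDR77 shRNA the median of that list was 0.16 (percentile 92.65), and 0.219 (percentile 97.505), just above the central 95%, with length and GC trends taken off. None of them passed over all genes tested, and 3 rose and 1 fell when adjusted over the list alone. Of the E2F and replication list, 7 of 38 members were at least 2-fold lower, including MCM4 (-1.85), POLA1 (-1.64), CCNE2 (-1.46) and UHRF1 (-1.28, and -0.046 with the other set's control).

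The WDR77 shRNA library had 568 genes at least 2-fold higher and 338 at least 2-fold lower than its own control among 13562 above the floor. S100P was at log2 3.42 ± 0.24 (10.7-fold), AGR2, a protein disulfide isomerase of secretory epithelia, at 3.03 ± 0.03, the tetraspanin gene TSPAN8 at 3.0 ± 0.06 and the adhesion gene MPZL2 at 3.37 ± 0.15. VAMP1, a vesicle SNARE, was at 4.02 ± 0.19, NDUFA1, a complex I subunit, at 3.33 ± 0.05, CYP3A5 at 2.90 ± 0.19, DPM3 at 2.75 ± 0.23 and TMEM160 at 2.67 ± 0.12. LOC649330 had the highest ratio, 4.75 ± 0.28, and is uncertain because it closely resembles HNRNPC and may share reads with it. Below 1 CPM in control 1 were LOC649330 (0.23), S100P (0.34), DPM3 (0.37), MPZL2 (0.84) and CYP3A5 (0.93). On the lower side were SOBP (-3.37 ± 0.14), TSPEAR (-2.99 ± 0.28), PRR29 (-2.88 ± 0.12), the amino acid transporter gene SLC7A8 (-2.75 ± 0.19), EMR3 (-2.43 ± 0.20), WDR77 itself (-2.43 ± 0.06) and ALAS2 (-2.42 ± 0.11). FCRL6 (-2.28 ± 0.22), PDE6H (-2.28 ± 0.17) and BAX, a pro-apoptotic BCL2 family gene (-2.24 ± 0.04), completed the 10 lowest. Control 1 over control 2 was 3.48 for SOBP, 2.84 for PRR29, 3.38 for ALAS2 and 1.12 for BAX, and against control 2 the ratios of SOBP and ALAS2 turned positive, at 0.12 and 0.96. Against control 2 PRR29 was at -0.033, PDE6H at -0.15, EMR3 at -0.32, SLC7A8 at -1.21, FCRL6 at -1.26 and BAX at -1.11, and among the highest LOC649330 was at 1.38, NDUFA1 at 1.21, VAMP1 at 2.5, CYP3A5 at 1.85, DPM3 at 1.59 and TMEM160 at 2.12. Larger against control 2 were AGR2 (5.15), TSPAN8 (4.20) and MPZL2 (3.89).

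Cholesterol biosynthesis genes were lower after WDR77 shRNA, with a median of -0.77 over 24 members (percentile 0), 22 of them below control and 7 at least 2-fold lower. FDFT1, squalene synthase, was at -1.53 (0.13 with the other set's control), DHCR7 at -1.39 and MVD at -1.09. After PRMT5 shRNA the list median was 0.09 (percentile 87.4), with MVD at -1.03. The same list was higher in control 1 than in control 2, by a median of 0.95, and against control 2 its WDR77 median was 0.29. In limma's test of either shRNA 0 of 24 members passed, and 2 fell when adjusted over the list alone, MVD and DHCR7. Hypoxia and glycolysis genes had a median of 0.49 over 29 members (percentile 100), 28 of them above control, and -0.03 after PRMT5 shRNA (percentile 40.3), with 3 members at least 2-fold higher in each. PFKFB3 had 1.27 and 0.34 (-0.068 after WDR77 shRNA with the other set's control), whereas ALDOC (0.90 and 1.11), CA9 (0.76 and 1.25) and SLC2A3 (0.58 and 1.12) were higher after PRMT5 shRNA than after WDR77 shRNA, an order that turned with the other set's control, where the PRMT5 ratios were -1.19, -0.51 and -0.082. Nuclear and structural noncoding RNAs had a median of 0.92 over 10 members (percentile 100), with GAS5 at 1.16 and SNHG5 at 1.32 (-0.43 with the other set's control), against 0.00 after PRMT5 shRNA. Genes reported in other cells as repressed by PRMT5 had a median of 0.53 over 12 members (percentile 99.9), and 0.11 after PRMT5 shRNA (percentile 86.6). The named members were above control in both, KLF4 at 1.10 and 0.97 (-0.27 after WDR77 shRNA with the other set's control), CDKN1B at 0.91 and 0.47, PDCD4 at 0.51 and 1.06 and DKK1 at 0.57 and 0.86 (-0.56 and -0.023 for CDKN1B and DKK1 after PRMT5 shRNA with the other set's control). Ribosomal protein genes had a median of 0.28 over 72 members (percentile 100), with RPS29 at 1.88 (0.062 with the other set's control), and after the trends with transcript length and GC content were taken off it was 0.03 (percentile 66.6). After PRMT5 shRNA the median was -0.09 (percentile 2), and -0.07 (percentile 5.14), inside the central 95%, with those trends taken off. In limma's test of either shRNA 0 members of these 4 lists passed over all genes tested, and 5, 2, 4 and 0 rose when adjusted over the list alone, in the order given.

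**Figure D3:**
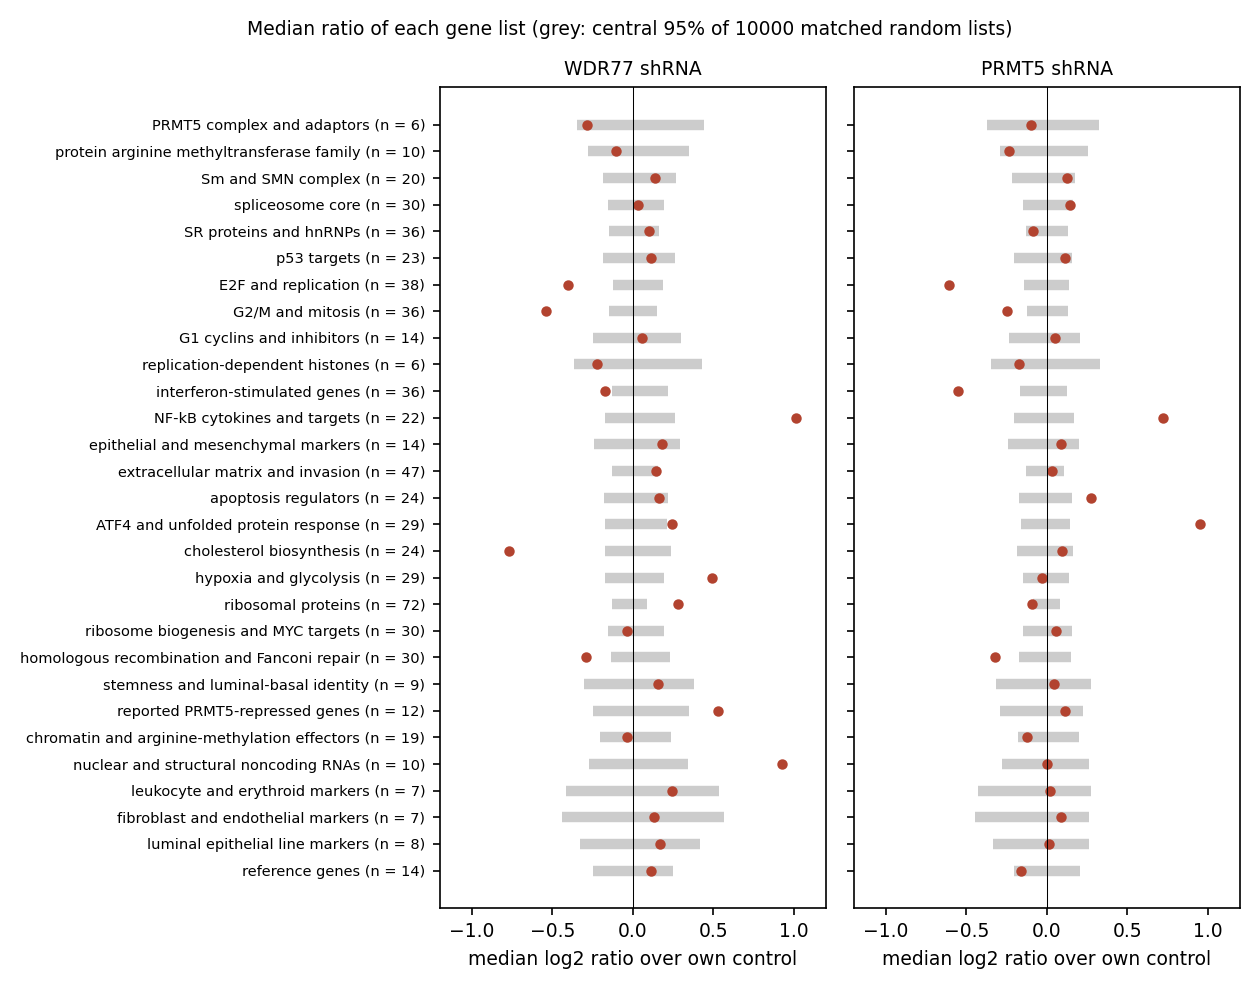
Median log2 ratio over own control (x axis) of each gene list (y axis, n is the members above the floor) after WDR77 shRNA (left) and PRMT5 shRNA (right); red points are medians and grey bars the central 95% of 10000 random lists matched on level. NF-kB genes lie above the grey bar in both panels (1.02 and 0.72) and E2F genes below it (-0.40 and -0.61), while cholesterol genes lie below it after WDR77 shRNA (-0.77).

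The next comparison asked which genes separated the knockdowns. The PRMT5 ratio exceeded the WDR77 ratio by at least 2-fold for 425 genes and fell short of it by as much for 877, again with no test. INSIG1, which restrains sterol synthesis (chromosome 7, 155089486 to 155101945), was at -2.22 ± 0.02 after WDR77 shRNA and 1.31 ± 0.03 after PRMT5 shRNA. ASNS was at 0.11 and 3.64, GDF15 at 1.43 and 4.68, TSPEAR at -2.99 and 0.18 and the keratin gene KRT34 at -1.75 and 1.40. In the other direction were VAMP1 (4.02 and -0.07), PKIB (1.72 and -2.0), NDUFA1 (3.33 and -0.18) and TSPAN8 (3.0 and -0.47), besides LOC649330 (4.75 and 0.27). INSIG1 depended on the control library: with the other set's control its ratios were 1.58 and -2.49.

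The scrambled controls, which carry the same kind of hairpin, were further apart from each other than either knockdown from its own control. Control 1 was at least 2-fold higher than control 2 for 1919 genes and at least 2-fold lower for 2784, of 13684 above the floor. The SD of the log2 ratio across genes was 1.2 between controls, 0.54 in the WDR77 pair and 0.45 in the PRMT5 pair. Of 59 listed replication-dependent histone genes, 10 were measured and 6 lay above the floor in both pairs. No row has fewer than 100 reads in both libraries of the PRMT5 set, so histone genes scarce there could be missing. The 6 were far higher in control 1, with a median of 4.51 (HIST1H2AC 5.59, HIST1H2BJ 4.62, HIST1H2BK 2.32), and within the pairs their medians were -0.22 and -0.17. With length and GC trends taken off, the WDR77 median was -0.58 (percentile 0.12), below the central 95%. Chromatin and arginine-methylation effectors were lower in control 1, at a median of -0.90 over 19 members (percentile 0.29). Spliceosome core genes had a median of -0.64 over 30 members (percentile 0.45), which was -0.12 (percentile 28.2), inside the central 95%, with length and GC trends taken off. The tables were scaled separately, so levels set across them are in CPM, scaled to each library's gene total. Against both controls together, limma called 0 genes for WDR77 shRNA, with 187 at an unadjusted p below 0.05, and 4 for PRMT5 shRNA. Of these 4, GDF15 (log2 4.71, adjusted p 0.0101) and EGR1 (4.32, 0.0370) rose and the histone genes HIST1H1E (-5.26, 0.00290) and HIST1H3B (-4.66, 0.0222) fell. All but GDF15 are named after their values were seen, and against its own control EGR1 was at 1.77, HIST1H1E at -0.99 and HIST1H3B at -0.66. Both histone genes lay below the floor in the PRMT5 pair, so their ratios there rest on low levels. Control 1 over control 2 was -5.11 for EGR1, 8.54 for HIST1H1E and 7.99 for HIST1H3B. The infinite prior of this fit leaves out each gene's own spread between the controls. For EGR1 and the histone genes the calls thus hold the distance between the sets. With median-of-ratios scaling limma called 0 genes in this PRMT5 test, with 257 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0721. On simulated libraries with the same control spread this test recovered 0% of genes changed 4-fold, so its low counts set no limit on the number of changed genes.

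**Figure D4:**
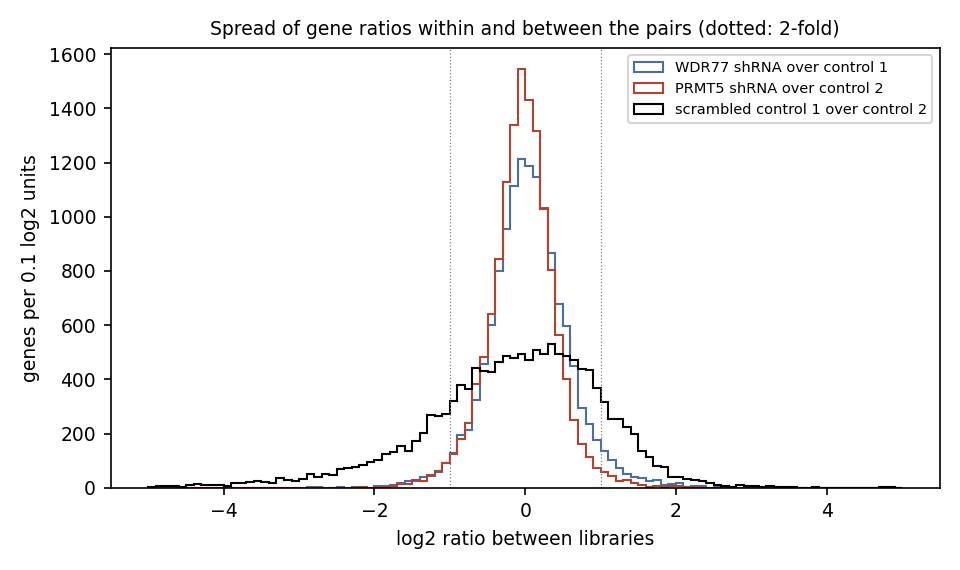
Distribution of gene log2 ratios (x axis, 0.1 log2 units per bin between -5 and 5; y axis, genes per bin) for WDR77 shRNA over control 1 (blue), PRMT5 shRNA over control 2 (red) and control 1 over control 2 (black), 1 library each; dotted lines mark 2-fold. The black curve is the widest, with an SD over all genes of 1.2 against 0.54 and 0.45.

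The medians of the splicing machinery lists, which include known PRMT5 substrates, lay inside the central 95% of random lists in both pairs. Sm and SMN complex genes had medians of 0.13 and 0.13 over 20 members (percentiles 79.2 and 92.9), with SNRPG at 1.07 and 0.03. Spliceosome core genes had 0.03 and 0.15 over 30 members (percentiles 57.2 and 96.4), and SR protein and hnRNP genes 0.10 and -0.09 over 36 members (percentiles 89.7 and 9.33). With length and GC trends taken off, the SR protein and hnRNP median after WDR77 shRNA was 0.18 (percentile 98.1), above that range. By limma's test of either shRNA 0 members of these lists passed, over all genes tested or adjusted over the list alone. Transcript usage, read as a RefSeq row's share of its gene's reads, moved by at least 0.2 in 14 of 6045 multi-row genes after WDR77 shRNA and 4 of 6050 after PRMT5 shRNA, against 68 of 6047 between the controls. The same row moved the same way in both knockdowns for 0 genes. The 4 genes after PRMT5 shRNA, named after their values were seen, were TMPO, where NM_003276 held 46.2% of reads against 24.4% in control, CREBZF (NM_001039618, 74.7% against 49.4%), CHM (NM_000390, 55.4% against 79%) and ZNF626 (NM_001076675, 46.1% against 69.6%). Isoform rows share reads, so these shares understate changes in single exons and show nothing about exons that no row separates.

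Several lists lay inside the central 95% of random lists in both pairs. These were p53 targets (medians 0.11 and 0.12 over 23 members), G1 cyclins and inhibitors (0.06 and 0.05 over 14), epithelial and mesenchymal markers (0.18 and 0.09 over 14), extracellular matrix and invasion genes (0.14 and 0.04 over 47), and ribosome biogenesis and MYC targets (-0.03 and 0.06 over 30). The protein arginine methyltransferase family (-0.10 and -0.24 over 10), PRMT5 complex and adaptors (-0.28 and -0.09 over 6), stemness and luminal-basal identity genes (0.15 and 0.05 over 9), and chromatin and arginine-methylation effectors (-0.04 and -0.12 over 19) did so too. With length and GC trends taken off, the median of PRMT5 complex and adaptors after WDR77 shRNA was -0.40 (percentile 0.95), below that range. That list includes the targeted genes WDR77 and PRMT5, and the methyltransferase family list includes PRMT5. Within the p53 list BBC3 was at 0.81 and 1.81, BAX at -2.24 and -0.03, and FDXR at -0.91 and -1.29. GDF15 rose in that list by limma's test of either shRNA over all genes tested, and 3 rose and 2 fell when adjusted over the list alone. CLDN4 (1.37 and 0.96, adjusted p 0.0274) rose among epithelial markers and CYR61 (0.83 and 1.44, adjusted p 0.0285) among extracellular matrix genes, where 3 and 1 rose when adjusted over the list alone. With the other set's control CYR61 after WDR77 shRNA turned to -1.95. Markers of other cell types also lay inside that range, with leukocyte and erythroid markers at 0.24 and 0.02 over 7, fibroblast and endothelial markers at 0.13 and 0.09 over 7, and luminal epithelial line markers at 0.17 and 0.01 over 8. Reference genes were at 0.11 and -0.16 over 14 members. Mitochondrially encoded mRNAs had 0 members in the tables.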

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

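Tests chosen only after results were seen are the length and GC trend for the number of genes higher after WDR77 shRNA and the test on overlapping genes. The lists of immediate-early genes, of clock genes and of RNAs without a poly(A) tail were also chosen then. The length and GC correction itself was also added after the data were seen.

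Ribosomal protein genes were noted because the knockdowns lay on opposite sides of their controls, with a median of 0.28 after WDR77 shRNA and -0.089 after PRMT5 shRNA. The same reason singled out 8 genes at least 2-fold higher after WDR77 shRNA and lower after PRMT5 shRNA, among them PKIB (1.72 and -2.0), and 6 genes the other way round, among them INSIG1 (-2.22 and 1.31). These counts are near the 11.2 and 4.58 that independent lists of those sizes would share. Neither difference was tested: a difference between the ratios over own controls takes all 4 libraries and leaves 0 residual degrees of freedom. A direct contrast of the knockdown libraries was not run, and it would include the distance between the sets.

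The first pattern weighed is the distance between the scrambled controls, 4703 genes at 2-fold, with histone genes far higher in control 1. The tables argue against counting error, since the highest of 20 Poisson simulations gave 0 genes. Across genes the control ratio fell with GC content (Spearman rho -0.51, against 0.25 in the WDR77 pair and 0.002 in the PRMT5 pair). Among the 13265 genes with a GC value, taking off the length and GC trend left 3429. Genes higher in control 1 went from 1838 to 1188 and genes lower from 2710 to 2241. The SD went from 1.2 to 1.06, so the trend accounts for part of the distance and not all of it. Genes that overlap no other gene were 2-fold apart in 34.5% of cases, against 34.4% of all genes, so overlapping genes counted differently in the tables do not account for it. For the histones, retention of RNAs without a poly(A) tail cannot be told apart from other causes, because only SCARNA12 of that class was in the tables, at 1.64. A difference between the sets in library preparation, culture density or passage remains open and was not tested, as the labels give no batch.

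The next pattern is the WDR77 pair, where ribosomal protein genes and more genes were higher than in the PRMT5 pair, an order of counts that turns with the other set's control (1855 against 2887) and with the mean of both controls (641 against 1264). With the length and GC trend taken off, the ribosomal protein median lay at percentile 66.6 of matched random lists, so the trend could account for that median. The trend does not account for the number of genes, since with it taken off 453 genes were at least 2-fold higher after WDR77 shRNA against 214 after PRMT5 shRNA. Counting error gave 0 such genes in the highest of 20 simulations. A response to loss of WDR77 stays open: limma's test against both controls called 0 genes, with 187 at an unadjusted p below 0.05, and recovered 0% of genes changed 4-fold in simulation.

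The last pattern is the NF-kB genes, higher in both knockdowns. The tables argue against a length and GC trend, since with it taken off the lower of the percentiles in the knockdowns was still 100. For culture state or harvest time that differed between each hairpin and its control, the prediction was met. Immediate-early genes, which answer to serum and handling, also lay at percentile 100 in both pairs. The list was written after JUNB, a member, was seen higher in both knockdowns, so its percentile is not independent support. Between the controls the immediate-early median was -1.08, control 1 over control 2. That list shares members with what a signalling response to PRMT5 or WDR77 loss could raise, so this value does not exclude such a response. Both explanations remain open.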

How the results depend on the processing

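The floor set at genes above the median level and the correction for length and GC content were chosen after seeing the data. The direction of each knockdown of its own target held with the other set's control, median-of-ratios scaling and the highest row per gene, the alternatives run for it. Scaling by median of ratios, dropping the floor and taking the highest transcript row left most counts within 1.5 times. The choice of control changed directions. With the other set's control 173 values were checked, of genes taken by the naming rule or printed in the text, though not every printed value. Of these 19 held, 134 moved and 20 reversed from at least 2-fold, and of 58 list medians 18 held, 36 moved and 4 reversed. Depth limits little here, since counting alone gave 0 genes at 2-fold in any pair. The alternative pseudocount was not run, because the log values took none.

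With the floor 5 times higher, fewer genes enter, and 310 were higher and 177 lower after WDR77 shRNA, 19 higher and 8 lower in both, and 228 and 504 apart (PRMT5 ratio above, WDR77 ratio above). With only genes above the median level these were 171 and 97 after WDR77 shRNA, 100 and 97 after PRMT5 shRNA, 1056 and 1434 between the controls, 5 and 3 in both, and 138 and 224 apart. The 3-fold rule, stricter by construction, gave 137 and 62, 42 and 35, 552 and 1487, 6 and 0, and 90 and 202 in the same order. With length and GC trends taken off, 1188 genes were higher in control 1.

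With the other set's control the counts were 1855 higher and 2488 lower after WDR77 shRNA, 2887 and 2295 after PRMT5 shRNA, 21 higher in both, and 4341 and 4045 apart, and the correlation turned to -0.807. The distance between controls then enters both ratios with opposite sign, which by construction lowers the correlation. It enters each gene ratio in the same way, so a reversal with that control does not by itself test the knockdown effect. Each knockdown resembled its own control more: log2 levels correlated across genes at r 0.973 in the WDR77 pair and 0.981 in the PRMT5 pair, against 0.871 between the controls. With the mean of both controls 943 were lower after WDR77 shRNA, 1264 higher and 830 lower after PRMT5 shRNA, 28 lower in both, and 2433 and 2051 apart, with a correlation of -0.408. Unchanged libraries simulated under that shared reference gave -0.991. The log2 ratio of PRMT5 with the other set's control was -0.65 after WDR77 shRNA and -2.72 after PRMT5 shRNA, and that of WDR77 was -2.69 and -0.98.

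Medians after WDR77 shRNA that reversed with the other set's control were those of G2/M genes (0.11), interferon-stimulated genes (0.62), NF-kB genes (-1.26) and cholesterol genes (0.29). Genes that reversed from at least 2-fold were SOBP (0.12), ALAS2 (0.96), CSF2 (-0.20), CXCL2 (-0.011), PER1 (-2.04), FAM111B (0.027), INSIG1 (1.58), IL6 (-2.23), CENPE (0.51), FDFT1 (0.13), PFKFB3 (-0.068), SNHG5 (-0.43), KLF4 (-0.27), EGR1 (-2.98), DUSP1 (-0.28) and CXCL1 (-2.07) after WDR77 shRNA, and INSIG1 (-2.49), ALDOC (-1.19), CA9 (-0.51) and SLC2A3 (-0.082) after PRMT5 shRNA. List medians above the central 95% of random lists numbered 3 after WDR77 shRNA and 7 after PRMT5 shRNA with that control. Why the controls differ was not tested.

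Genes with a changed transcript share were 6 (WDR77 pair) and 42 (controls) with the floor 5 times higher, and 3, 0 (PRMT5 pair) and 19 with a share change of 0.3. The limma test of either shRNA called 4 genes with median-of-ratios scaling (4 higher, 0 lower), 107 with the highest row per gene and 0 without the control-set term. The fits with 1 library left out had no control-set term either. Each left a lone library in a group, assumed to vary like the rest, so they do not retest those calls. The PRMT5 test against both controls called 0 genes in limma with median-of-ratios scaling, with 257 at an unadjusted p below 0.05. Apart from the constructions named, the cause was not tested.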

Other observations

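The lists of clock genes and immediate-early genes below were written after JUNB, PER1 and NR1D1 were seen among the genes higher in both knockdowns, and before their other members were looked up. Clock genes under E-box and D-box control, which drive the daily rhythm of transcription, had a median log2 ratio of 0.53 after WDR77 shRNA and 0.88 after PRMT5 shRNA over 14 members (percentiles 99.9 and 100 of 10000 matched random lists, as a description of these libraries). After PRMT5 shRNA all 14 were above control. NR1D1 (2.21 and 1.76) and PER1 (1.44 and 1.64) rose in limma's test of either shRNA. DBP (1.21 and 0.55), TEF (0.02 and 1.35) and CRY2 (0.73 and 1.01) did not pass and were chosen after their values were seen. Between the controls the list median was -0.64, control 1 over control 2. With the other set's control CRY2 (-0.86) and PER1 (-2.04) turned after WDR77 shRNA and NR1D1 fell to 0.12, while DBP (1.75) and TEF (0.58) were larger. After PRMT5 shRNA DBP (0.0096) and TEF (0.79) were then smaller, and PER1 (5.12), NR1D1 (3.85) and CRY2 (2.60) larger.

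Immediate-early genes, the early transcriptional answer to growth factors and stress, had medians of 0.84 and 0.59 over 20 members, both at percentile 100, with 8 and 5 members at least 2-fold higher. EGR1 (2.13 and 1.77), DUSP1 (1.28 and 2.04) and JUNB (1.58 and 1.5) rose in the same test. The list overlaps others, since MYC, KLF4 and ATF3 stand in lists described above. Between the controls its median was -1.08.

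Among transcript shares, which moved by at least 0.2 in 14 genes after WDR77 shRNA, SMARCB1 had 79.6% of its reads on NM_003073 against 59.5% in control, and CASC1 79.4% on NM_001082972 against 48.3%. Both were chosen after their values were seen.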
